A study of Mus musculus with 12 samples.

How the data were processed

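RNA sequencing was done on macrophages grown from mouse bone marrow. Per the labels, bone marrow cells were grown for 6 days with 10 ng/mL M-CSF, the growth factor that drives marrow progenitors to become macrophages. The donor mice either lacked Ptprz1, which encodes protein tyrosine phosphatase receptor type Z (KO), or were wild type (WT). Cells of each genotype were left untreated (control), treated for 24 h with 100 ng/mL LPS, a bacterial lipopolysaccharide, and 10 ng/mL IFNγ (called M1 in the labels), or treated for 24 h with 20 ng/mL IL-4 (called M2 in the labels). This gives 6 groups of 2 libraries, 12 in all, and sample titles set the groups and library numbers. Titles of WT samples begin with B6, and the genotype labels match the titles. The strain label names the same targeted Ptprz1 strain for every sample, WT included. Total RNA was extracted with an innuPREP kit, and libraries were prepared with the directional NEBNext Ultra II kit, per the labels' protocols. The labels do not say whether libraries of a group came from separate animals or separate cultures, so the p-values measure only the spread between these samples, which may be technical.

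The deposited table gives estimated counts for 55891 Ensembl gene identifiers in each library. Per the submitters' processing notes, Salmon 1.10.2, R 4.4.1, DESeq2 1.45.3 and FastQC 0.11.9 were used with genome build GRCm39, with no role given for each. Salmon estimates transcript abundance, and every deposited value was a whole number, so the values were taken as rounded estimates and used as they stood. The transcript annotation, read trimming, and whether strand was used in counting are not given in the sources used here. Genes that overlap or lie antisense to each other, and genes of families with near-identical copies, therefore have uncertain counts. Of the identifiers, 51425 (92.0%) were matched to a gene symbol and a position in GRCm38 with GENCODE release M21. All coordinates are GRCm38 and were not converted to the authors' build. Every sample column was assigned to a sample, with 0 left over.

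Total counts ran from 13665607 (KO LPS+IFNγ library 2) to 19555600 (KO control library 1). At these depths, 3 counts correspond to between 0.138 and 0.290 CPM (counts scaled by library size), and this was used as the limit for a gene with no counts. A fold against a group in which no library had a count is given as a lower bound, set against 3 counts in the shallowest library of that group. Such limits cover counting error only. The 20 most abundant genes took between 15.9% and 18.1% of the counts. In every group, the difference between the libraries exceeded sampling noise in a chi-square comparison of genes with at least 20 counts summed, so no library was treated as a repeat of another. The chi-square per gene was 7.10, 7.81 and 15.6 between WT libraries under control, LPS+IFNγ and IL-4, and 48.4, 53.8 and 54.9 between KO libraries.

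Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr, leaving 13525 genes, and libraries were scaled with TMM factors, which ran from 0.756 to 0.833 in LPS+IFNγ libraries and from 1.09 to 1.16 in the others. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries, which leaves 6 residual degrees of freedom. The prior degrees of freedom were 3.36 and the common dispersion was 0.0382. Quasi-likelihood F tests, all two-sided, were made for 10 contrasts. These were KO against WT within each treatment and as the mean over the 3 treatments, LPS+IFNγ or IL-4 against control within each genotype, and the genotype by treatment interaction for each stimulus. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistics, and CPM values are means ± SD over the libraries stated, which are 2 unless given.

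A total of 30 gene lists were tested: M1 markers, M2 markers, interferon-stimulated genes, IFNγ-induced GTPases, MHC class II, MHC class I, chemokines, Toll-like receptor and NF-κB genes, glycolysis, the TCA cycle and oxidative phosphorylation, cholesterol synthesis, lipid handling, core macrophage genes, genes of the PTPRZ axis (ligands, partner receptors and relatives of the phosphatase), repair and fibrosis, oxidative stress, the cell cycle, endoplasmic reticulum (ER) stress, immediate early and heat shock genes, mitochondrially encoded transcripts, sex-linked transcripts, genes near Ptprz1, and markers of granulocytes, B cells, T and NK cells, dendritic cells, mast cells and basophils, erythroid cells and megakaryocytes, stromal cells, and osteoclasts. Lists were compared with the other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the 30 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Members that passed the per-gene test were counted with adjustment over all genes and, in addition, adjusted over the list alone. In a genotype or interaction contrast, list medians were also computed with members that had no counts in a group set to the floor of that group.

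The groups, contrasts, lists and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule takes Ptprz1 in every library, and per contrast the 8 largest rises and 8 largest falls among genes with an adjusted p below 0.05, a mean log2 CPM of at least 1, an official symbol and no overlap between the libraries of the groups. The requirement of no overlap was not applied to interactions. Where fewer than 16 genes pass, the rule takes all that pass with a mean log2 CPM of at least 1. It adds the 3 tested members with the largest absolute log2 fold change of each list described, whether or not they pass, and genes of the sex-linked list and of the list of Ptprz1 neighbours that pass in any genotype contrast. Which lists are described for which contrast was chosen after the values were seen. The text names a part of the genes the rule takes, with preference for calls that held when single libraries were left out. Some of these genes are not reported here.

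Alternatives were DESeq2 size factors within edgeR, no filter on low counts, a stricter filter of at least 1 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, a fit to the libraries of 1 contrast only, 2 models with the library number as a block, a minimum absolute log2 fold change of 1, and leaving out each of the 12 libraries in turn. The density of called genes around Ptprz1 was tested with Fisher's exact test in a window of 20 Mb, with 5 and 50 Mb as alternatives. A further 3 alternatives were chosen after seeing the data: leaving out genes of the X and Y chromosomes, and leaving out together the 3 KO libraries numbered 1 or the 3 numbered 2. Within each genotype, libraries numbered 2 were also compared with libraries numbered 1 in a model that keeps treatment as a term, likewise chosen after seeing the data. The number of genes called between KO and WT was also counted for other divisions of the libraries that keep 2 against 2 within each treatment, and, chosen after seeing the data, so was the number of autosomal genes with p-values adjusted over these alone.

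The procedures were tested on simulated data with the depths and means of these libraries and 200 changed genes. Simulated libraries were drawn independently, with the same dispersion per gene in both genotypes. In the real data, same-numbered libraries of a genotype deviated together, and KO pairs differed more than WT pairs. The shares and counts below may therefore not hold for these data. For KO against WT in control cells (13299 genes tested), 2.99%, 53.7% and 86.4% of genes changed by a log2 fold of 0.5, 1 and 2 were recovered. For the mean over treatments, the recovered shares were 38.8%, 92.5% and 95.5%. For the LPS+IFNγ interaction, 80.5% of 200 genes simulated with a log2 difference of 2 were recovered among 13293 genes tested, and 0 of 13299 genes were called by edgeR when none was simulated to differ. Before the low-count filter, 13295 genes were simulated without a change. Of these, 4, 7, 7 and 7 were called for KO against WT in control, LPS+IFNγ, IL-4 and for the mean.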

Results

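The series asks how loss of Ptprz1, a receptor-type tyrosine phosphatase, changes macrophages in the setting of macrophage-mediated kidney injury. Gene expression was measured by RNA sequencing in bone marrow derived macrophages of KO and WT mice, left as control or treated for 24 h with LPS+IFNγ or IL-4. Each of the 6 groups had 2 libraries. Total counts per library ran from 13665607 in KO LPS+IFNγ library 2 to 19555600 in KO control library 1. The first principal component of log2 CPM, with 73.9% of the variance, parted LPS+IFNγ libraries from the rest, and the next 2 components held 7.56% and 6.50%.

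Ptprz1, the targeted gene (chromosome 6, 22875502 to 23052916, GRCm38), had 0 counts in 11 of the 12 libraries. The exception was WT IL-4 library 2, with 7 counts or 0.344 CPM. A count of 0 allows a level of up to 0.138 to 0.290 CPM, depending on the library. The gene did not pass the filter on low counts, and WT control and WT LPS+IFNγ libraries had no counts either, so these RNA data cannot check the knockout.

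The libraries of the 2 genotypes differed in sex-linked transcripts. Xist, the long RNA that silences an X chromosome in female cells, was present in all 6 WT libraries (449 ± 170 CPM, SD, n = 6) and had 0 counts in all 6 KO libraries, at least 1548-fold lower. The Y-linked genes Ddx3y, an RNA helicase (96.0 ± 10.8 CPM, SD, n = 6), Eif2s3y, a translation initiation factor subunit (37.0 ± 10.5 CPM), Uty, a histone demethylase relative (24.9 ± 1.17 CPM), and Kdm5d, a histone demethylase (22.2 ± 6.07 CPM), were present in all 6 KO libraries. They had 0 counts in all 6 WT libraries, so they were at least 470-fold, 181-fold, 122-fold and 109-fold higher in KO libraries. All 12 libraries had the sex-linked transcripts of 1 sex only, and sex and genotype coincided in this set. In each of the 4 genotype contrasts, 4 of the 5 sex-linked transcripts were higher and 1 was lower, over all genes and adjusted over the list alone. The camera test of this list held with an estimated correlation (adjusted p = 0.00533 in control, 0.00827 in LPS+IFNγ, 0.0029 in IL-4 and 0.00722 for the mean).

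Untreated KO and WT macrophages were compared to ask what loss of Ptprz1 does without a stimulus. Cndp2, a cytosolic dipeptidase, fell from 446 ± 7.63 CPM in WT to 61.4 ± 7.52 CPM in KO libraries (SD, n = 2 each; log2 fold change −2.86 ± 0.17, SE; adjusted p = 9.0e-05). Met, the receptor for hepatocyte growth factor, fell from 11.3 ± 0.0314 to 2.33 ± 0.227 CPM (−2.27 ± 0.17, adjusted p = 3.71e-04), and the long noncoding RNA Gm20186 fell from 16.2 ± 1.06 to 1.81 ± 0.698 CPM (−3.15 ± 0.26, adjusted p = 8.17e-04). Gdf3, a ligand of the TGF-β family, fell from 47.5 ± 4.63 to 21.6 ± 2.34 CPM (−1.14 ± 0.12, adjusted p = 0.00661). Neat1, the long RNA that organises nuclear paraspeckles, fell from 364 ± 78.5 to 154 ± 7.01 CPM (−1.24 ± 0.17, adjusted p = 0.0403). These 5 genes and the 5 sex-linked transcripts made up the 10 genes called in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 higher and 6 lower, and 1011 genes had an unadjusted p below 0.05 against 676 expected by chance. DESeq2 called 68, and edgeR without the low-count filter 107. Fitted on its own 4 libraries, the contrast called 4 genes, with adjusted p = 0.179 for Met, 0.331 for Gm20186, 0.425 for Gdf3, 0.498 for Neat1, and 0.0648 for both Kdm5d and Eif2s3y. The count was 49 without KO control library 2. Gdf3 was not called without WT control library 1 (adjusted p = 0.141) or KO control library 1 (0.0855). Neat1 was not called without any library except WT control library 2 (0.0567 to 0.348) or with DESeq2 size factors (0.0511).

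In the same comparison, interferon-stimulated genes had positive log2 fold changes in all 34 members tested, with a median of 1.37. No member passed edgeR's test over all genes or adjusted over the list alone, while 20 had an unadjusted p below 0.05 and DESeq2 called 1. The camera test gave an adjusted p of 3.2e-10, and adjusted p = 0.723 with an estimated correlation. A single library carried this: Ifit3, an antiviral interferon-induced protein, was at 36.5 and 2.10 CPM in KO and at 1.80 and 3.30 CPM in WT libraries (2.92 ± 1.04, adjusted p = 0.666), and Irf7, a transcription factor of the interferon response, was at 48.8 and 6.53 CPM in KO and at 7.58 and 7.59 CPM in WT libraries. Without KO control library 1, the direction of the list reversed (camera adjusted p = 0.924), and without KO control library 2, Ifit3 and Ifi44 passed (adjusted p = 0.0257 and 0.0121). The cholesterol synthesis list had positive values in 23 of 24 members (median 0.37, camera adjusted p = 1.16e-05, and adjusted p = 0.723 with an estimated correlation), again with 0 members called by edgeR over all genes or adjusted over the list alone, 7 at an unadjusted p below 0.05 and 0 by DESeq2. Its values included 0.76 ± 0.30 for Sqle (squalene epoxidase) and 0.69 ± 0.36 for Hsd17b7. Without KO control library 2, the camera call was lost (0.193).

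After LPS+IFNγ, KO libraries again had less Cndp2 (152 ± 15.0 against 1324 ± 6.02 CPM in WT, SD, n = 2 each; log2 fold change −3.12 ± 0.17, SE; adjusted p = 1.06e-04) and less Gdf3 (3.18 ± 0.0148 against 9.24 ± 0.0339 CPM; −1.54 ± 0.15, adjusted p = 0.00323). Rab4a, a small GTPase of early endosome recycling, was higher in KO libraries (3.46 ± 0.589 against 0.578 ± 0.0502 CPM; 2.56 ± 0.29, adjusted p = 0.0113). Met was at 88.4 ± 7.37 CPM in KO and 167 ± 16.9 CPM in WT libraries, with a log2 fold change of −0.92 ± 0.13 that did not pass (adjusted p = 0.0754). Together with the sex-linked transcripts, edgeR called 8 genes, 5 higher and 3 lower. An unadjusted p below 0.05 was found for 1119 genes, against 676 expected by chance. The ER stress list had positive values in 21 of 24 members (median 0.26, camera adjusted p = 0.00213, and adjusted p = 0.986 with an estimated correlation), with 0 called by edgeR over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 5 members were higher and 1 was lower, and DESeq2 called 0. Its member Chac1 was at 1.43 ± 0.80, Creld2 at 0.57 ± 0.22 and Asns, asparagine synthetase, at 0.79 ± 0.42, which reversed to −0.02 without KO LPS+IFNγ library 2, where the camera call was also lost (0.334). DESeq2 called 34 genes, and edgeR without the low-count filter 81. With all libraries, Met passed in both of these fits (adjusted p = 4.37e-05 in DESeq2 and 0.00141 in edgeR without the filter). Rab4a was not called without WT LPS+IFNγ library 1 (0.184) or 2 (0.183) or KO LPS+IFNγ library 2 (0.0639), and with the libraries of this contrast alone it had an adjusted p of 0.764, as did Gdf3.

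After IL-4, the genes lower in KO libraries were Cndp2 (73.5 ± 15.6 against 463 ± 41.1 CPM in WT, SD, n = 2 each; log2 fold change −2.66 ± 0.17, SE; adjusted p = 1.63e-04), Met (4.88 ± 0.725 against 20.1 ± 2.59 CPM; −2.04 ± 0.15, adjusted p = 4.32e-04), Gm20186 (2.94 ± 1.02 against 17.6 ± 1.99 CPM; −2.59 ± 0.25, adjusted p = 0.00291) and Gdf3 (17.5 ± 0.805 against 39.3 ± 1.40 CPM; −1.17 ± 0.12, adjusted p = 0.00591). With the sex-linked transcripts, these were the 9 genes called by edgeR, 4 higher and 5 lower. An unadjusted p below 0.05 was found for 453 genes, against 676 expected by chance. M2 markers were negative in all but 3 of 27 members (median −0.36, camera adjusted p = 8.64e-05, and adjusted p = 0.0844 with an estimated correlation). Over all genes edgeR called 0 of them, 1 was lower adjusted over the list alone, 3 were lower at an unadjusted p below 0.05 and DESeq2 called 0. Mean log2 CPM over the list was 5.24 and 4.79 in KO libraries 1 and 2 and 5.49 and 5.57 in WT libraries, and the median was −0.20 without KO IL-4 library 2 (camera adjusted p = 0.00723) and −0.58 without KO IL-4 library 1. Adjusted over the list alone, 6 were lower without KO IL-4 library 1 and 0 without KO IL-4 library 2 or any 1 of the WT libraries, and at an unadjusted p below 0.05 the count ran from 1, without either WT IL-4 library, to 9, without KO IL-4 library 1. Examples were Chil4, a chitinase-like lectin (−1.71 ± 0.74), and Ccl22, a chemokine of alternatively activated macrophages (−1.52 ± 1.21). MHC class II genes were negative in all but 2 of 11 members (median −0.80, camera adjusted p = 0.00473, and adjusted p = 0.781 with an estimated correlation), including H2-Eb1 (−1.12 ± 0.98) and its transactivator Ciita (−1.05 ± 1.03). EdgeR called 0 of them over all genes or adjusted over the list alone, 0 had an unadjusted p below 0.05 and DESeq2 called 0. Mean log2 CPM over the list was 3.97 and 2.39 in KO and 4.04 and 4.11 in WT libraries, and the camera call was lost without KO IL-4 library 2 (0.426). Mitochondrially encoded transcripts had a median of −0.33 (camera adjusted p = 0.00201, and adjusted p = 0.794 with an estimated correlation), with a mean log2 CPM of 9.51 and 8.21 in KO and 9.23 and 9.49 in WT libraries. Their median was 0.16 without KO IL-4 library 2 (0.196), −0.21 without WT IL-4 library 2 (0.0512) and −0.98 without KO IL-4 library 1 (4.38e-09). Gdf3 was not called without WT IL-4 library 1 (0.1) or 2 (0.0646) or KO IL-4 library 2 (0.111). DESeq2 called 18 genes, and edgeR without the low-count filter 33. The count was 20 without KO IL-4 library 1. Fitted on its own 4 libraries the contrast called 5 genes, with Cndp2 at 0.0709, Met at 0.209 and Gm20186 and Gdf3 at 0.302.

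The mean difference between KO and WT over the 3 treatments uses all 12 libraries and takes the 6 of a genotype as independent, which the labels do not establish. Differences between libraries numbered 2 and 1 correlated above 0.1 in all 6 same-genotype pairs of groups (lowest 0.170). The SEs and p-values of this contrast may therefore be too small. Over all pairs of groups, across genotypes too, 14 of 15 correlated above 0.1. A difference by number that both genotypes share would instead make the SEs too large. With the number as a block, edgeR called 173 genes, but library numbers are not established to pair the samples. Cndp2 (chromosome 18, 84667465 to 84685702) was lower by a log2 fold change of −2.88 ± 0.098 (SE, adjusted p = 2.08e-06), Met (chromosome 6, 17463800 to 17573980) by −1.74 ± 0.088 (1.28e-05), Gm20186 (chromosome 6, 18845910 to 18848207) by −2.03 ± 0.14, and Gdf3 (chromosome 6, 122605403 to 122610087) by −1.28 ± 0.075 (3.87e-05). Rab4a was higher by 1.52 ± 0.15 (adjusted p = 0.00236). Eya1, a transcriptional coactivator with phosphatase activity (−1.45 ± 0.18, adjusted p = 0.0126), Btbd2 (−0.81 ± 0.10, adjusted p = 0.0131) and Eps8l1, an actin-regulating protein (−1.22 ± 0.17, adjusted p = 0.0268), were also lower. In all, edgeR called 23 genes, 6 higher and 17 lower: 5 on the X chromosome, 5 on the Y chromosome, 12 on autosomes and 1 without a position. An unadjusted p below 0.05 was found for 1532 genes, against 676 expected by chance. A total of 7 genes, the 5 sex-linked transcripts with Cndp2 and Gdf3, were called under each of the 3 treatments. DESeq2 called 94, and edgeR without the low-count filter 312. Leaving out libraries moved the count in both directions, but such fits leave 1 library in a group, with its spread taken from other groups. Eya1 was not called without WT control library 1, WT LPS+IFNγ library 2, KO LPS+IFNγ library 2 or either WT IL-4 library (0.0514 to 0.0755). Btbd2 was not called without either WT control library, KO control library 2, WT LPS+IFNγ library 1, KO LPS+IFNγ library 2 or either WT IL-4 library (0.061 to 0.0767), nor Eps8l1 without any library except KO LPS+IFNγ library 1 or KO IL-4 library 1 (0.0617 to 0.142).

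**Figure D1:**
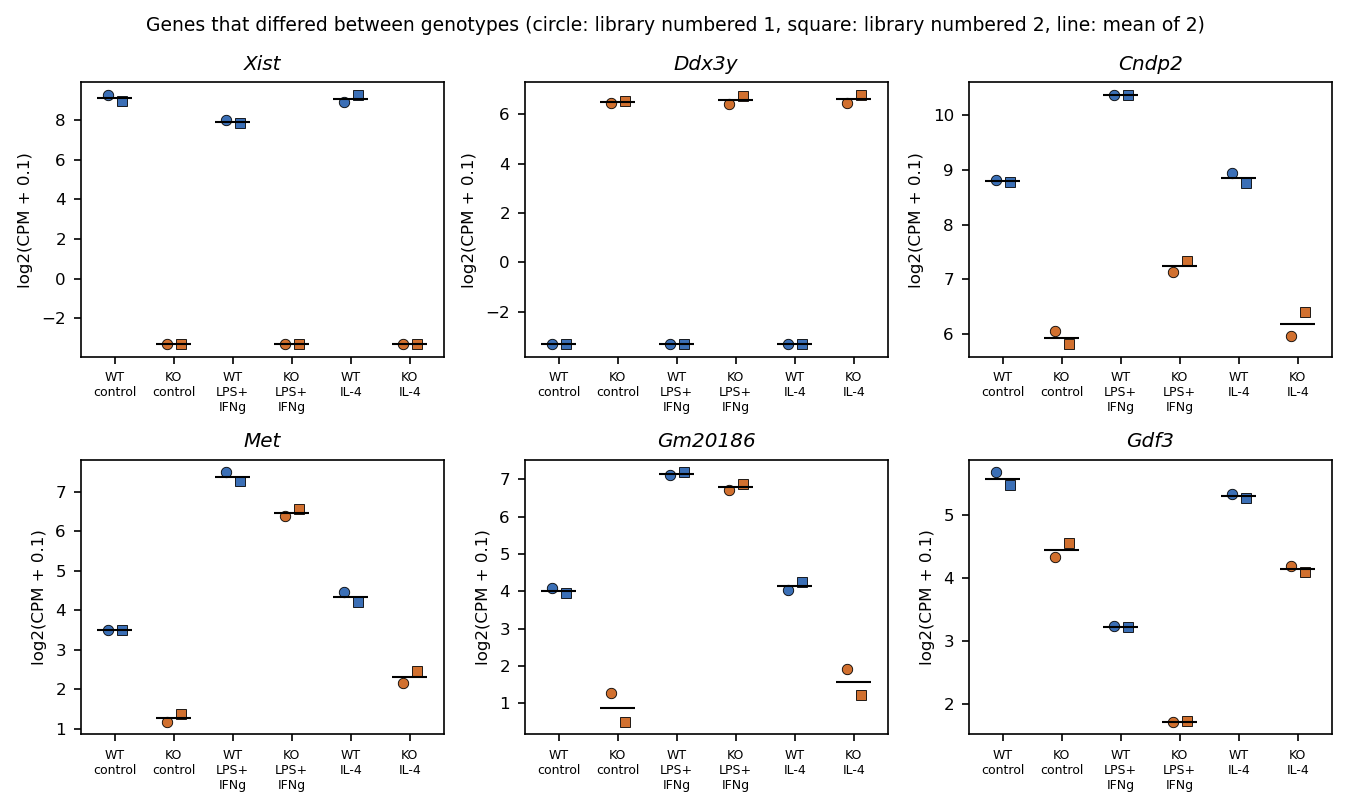
Expression of genes that differed between KO and WT macrophages, as CPM on a log axis with 0.1 CPM added, per library in the 3 treatments. Cndp2 lies between 61.4 and 152 CPM in KO group means and between 446 and 1324 CPM in WT group means.

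Genes near Ptprz1 were examined because a targeted allele can carry flanking DNA of the strain in which it was made. Of the 12 autosomal genes called for the mean, 3 lay on chromosome 6: Gm20186 at 4.03 Mb from Ptprz1, Met at 5.30 Mb and Gdf3 at 99.6 Mb. Within 20 Mb of Ptprz1, 2 of 138 tested genes were called, against 21 of 13387 elsewhere (Fisher's exact test, two-sided, p = 0.0227). Fisher's exact test gave p = 0.00441 in control and 0.00355 in IL-4 cells. In LPS+IFNγ cells, 0 of the 138 were called by edgeR (Fisher's exact test, p = 1). Met did pass after LPS+IFNγ in DESeq2 and in edgeR without the low-count filter. In the list of 38 tested Ptprz1 neighbours, fixed without reference to these values, Met was the member that fell in control, in IL-4 and for the mean.

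Markers of stromal cells, mostly fibroblast genes such as collagens but also the endothelial markers Pecam1, Cdh5 and Kdr, tended to higher values in KO libraries. They also differed between libraries of 1 genotype. Their median log2 fold changes were 1.06 in control, 1.49 after LPS+IFNγ, 1.56 after IL-4 and 1.31 for the mean, positive in 14, 13, 13 and 13 of 16 members. No member passed edgeR's test over all genes in any of the 4 contrasts. For the mean, 7 of 16 were higher adjusted over the list alone, 10 at an unadjusted p below 0.05, and DESeq2 called 2. In the single treatments the unadjusted counts were 1, 2 and 4 and DESeq2 called 0. Camera adjusted p was 0.00487, 0.0171, 9.26e-04 and 1.38e-04, and adjusted p = 0.723, 0.986, 0.794 and 0.648 with an estimated correlation. Postn, periostin of the extracellular matrix, was at 3.56 ± 1.26, 4.42 ± 1.64, 3.45 ± 1.24 and 3.81 ± 0.80 (adjusted p = 0.666, 0.582, 0.980 and 0.248). Col1a1, the α1 chain of type I collagen, was at 22 and 123 CPM in WT control libraries 1 and 2 and at 151 and 416 CPM in KO control libraries 1 and 2. The camera call was lost in control without WT library 1 (0.769) or KO library 2 (0.283), after LPS+IFNγ without WT library 1 (0.230) or KO library 1 (0.111), and after IL-4 without WT library 1 (0.254). MHC class II genes had a median of −0.69 for the mean (camera adjusted p = 0.0253, and adjusted p = 0.648 with an estimated correlation). Mean log2 CPM over the list was low mainly in KO libraries numbered 2: 2.05 in control, 3.88 after LPS+IFNγ and 2.39 after IL-4. KO libraries numbered 1 had 3.51, 4.36 and 3.97. WT libraries had 3.64 and 3.54, 4.47 and 4.29, and 4.04 and 4.11 under the same treatments. Of its 11 members, 0 were called by edgeR over all genes or adjusted over the list alone, 0 at an unadjusted p below 0.05 and 0 by DESeq2. That camera call was lost without KO LPS+IFNγ library 1 (0.0681) or 2 (0.0643) or KO IL-4 library 2 (0.0912).

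**Figure D2:**
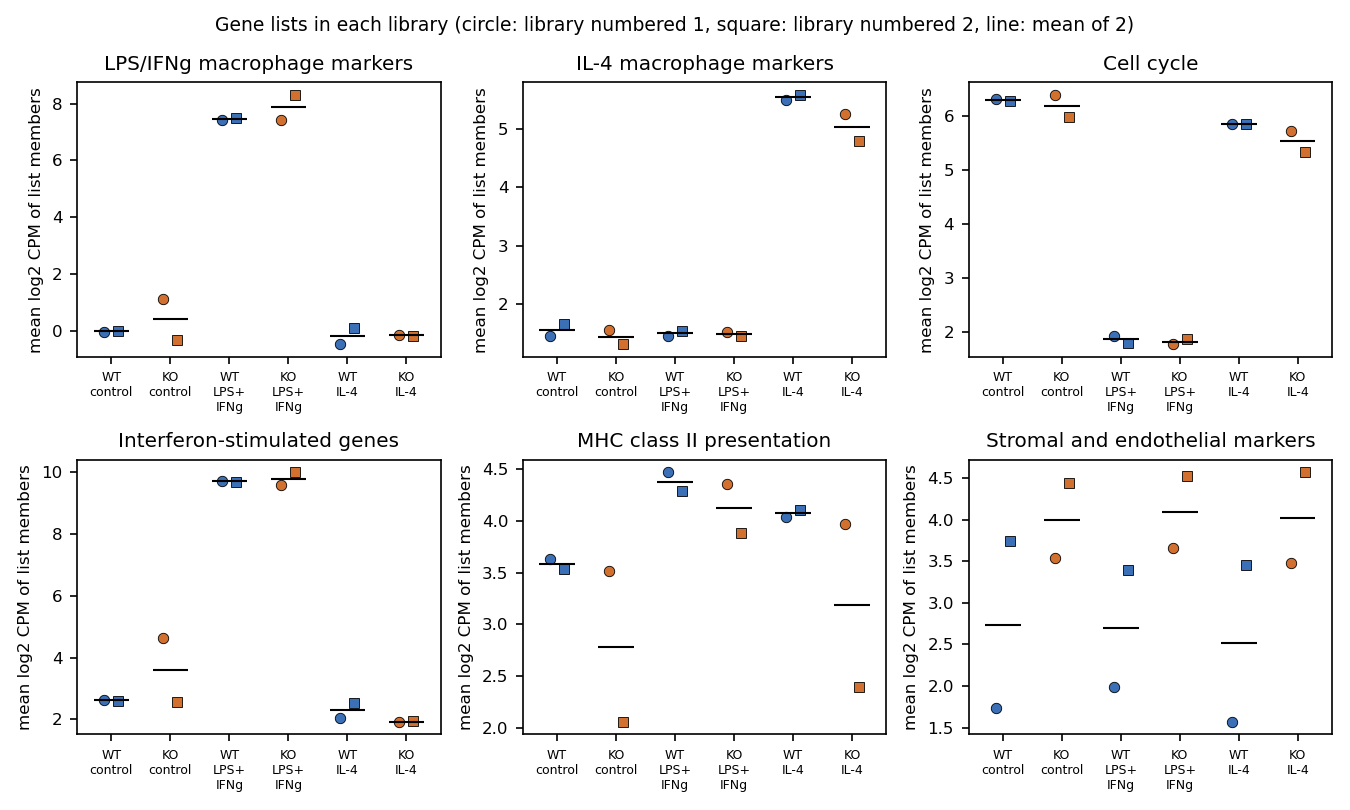
Mean log2 CPM over the members of selected gene lists, per library in the 6 groups. Stromal markers span 1.57 to 4.57 over the libraries and lie higher in library 2 than in library 1 of every group.

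LPS+IFNγ was compared with control to describe the M1 response in WT macrophages. Cxcl9, a chemokine induced by IFNγ, rose from 0 to 1214 ± 161 CPM (SD, n = 2), at least 8215-fold (adjusted p = 1.12e-06). Nos2, the inducible nitric oxide synthase, rose from 1 count in all to 5251 ± 652 CPM (adjusted p = 1.54e-07), and Il12b, the p40 subunit of IL-12 and IL-23, from 0 to 120 ± 4.86 CPM, at least 813-fold (adjusted p = 3.62e-04). Cxcl10, another interferon-induced chemokine, rose from 0.268 ± 0.170 to 2680 ± 115 CPM (log2 fold change 13.25 ± 0.71, SE). Genes of cell division fell: Ccnb2, a mitotic cyclin, went from 63.7 ± 3.06 CPM to 0, at least 311-fold lower (adjusted p = 8.17e-05), Spag5, a spindle protein, was at least 270-fold lower, Esco2, a cohesin acetyltransferase, at least 177-fold lower, and E2f7, an atypical E2F repressor, at least 143-fold lower. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7348 genes, 3700 higher and 3648 lower.

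By gene group, all 29 M1 markers, all 34 interferon-stimulated genes, all 20 MHC class I genes and 19 of 20 IFNγ-induced GTPases rose in WT macrophages, with the same counts adjusted over the list alone. Mx1, an antiviral GTPase, rose by 11.98 ± 0.84 to 1712 ± 1.69 CPM, Iigp1, an immunity-related GTPase, by 11.26 ± 0.63 to 797 ± 42.9 CPM, and H2-Q4 by 5.07 ± 0.31. Counts of MHC genes are uncertain because their sequences are similar. The camera adjusted p-values were 1.2e-13, 3.28e-15, 2.61e-11 and 1.93e-11 in the order M1, interferon, MHC class I and GTPases. With an estimated correlation the 4 calls were lost (adjusted p = 0.282, 0.409, 0.282 and 0.282 with an estimated correlation). Fry called all 4 (adjusted p = 5.78e-06, 7.50e-05, 1.49e-05 and 5.78e-06), among 25 of the 30 lists of this contrast. Of 40 Toll-like receptor and NF-κB genes, 33 rose and 1 fell, with the same counts adjusted over the list alone. These included the pattern recognition receptor Nod2 (4.11 ± 0.25), Casp4, encoding caspase-11 (3.96 ± 0.28), and Nod1 (3.84 ± 0.30). Of 21 chemokines, 14 rose and 4 fell (14 and 5 adjusted over the list alone), with Ccl8 at least 49.9-fold higher. Camera adjusted p was 2.0e-09 and 0.00215 for these 2 lists, and adjusted p = 0.282 with an estimated correlation for both.

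Metabolic genes and the cell cycle also changed in WT macrophages. Of 25 glycolysis genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone). Pfkfb3, which makes the activator of phosphofructokinase, rose from 30.8 ± 0.919 to 2757 ± 220 CPM (6.49 ± 0.24), Slc16a3, a lactate exporter, by 3.89 ± 0.27 and Slc2a1, the glucose transporter GLUT1, by 3.45 ± 0.30. Of 35 cell cycle genes, 32 fell and 2 rose, also adjusted over the list alone, and Ccna2, cyclin A2, went from 141 ± 0.922 CPM to 2 counts in all. Of 24 cholesterol synthesis genes, 16 fell and 1 rose (18 and 1 adjusted over the list alone), among them Sqle (−2.88 ± 0.34) and Idi1, isopentenyl diphosphate isomerase (−2.72 ± 0.29). Of 26 oxidative stress genes, 15 rose and 7 fell, also adjusted over the list alone. Slc7a11, the cystine transporter, rose by 5.17 ± 0.32, Sod2, the mitochondrial superoxide dismutase, by 4.10 ± 0.23, and Hmox1, heme oxygenase 1, from 369 ± 1.5 to 6274 ± 51.1 CPM. Camera adjusted p was 5.58e-05, 1.29e-13, 4.18e-04 and 0.0253 for these 4 lists, and adjusted p = 0.282, 0.266, 0.556 and 0.282 with an estimated correlation.

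Other lists split into rising and falling members in WT macrophages, and the camera test did not pass for any of the 5 that follow. Of 29 lipid handling genes, 6 rose and 13 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.205); Lpl, lipoprotein lipase, fell from 8257 ± 178 to 641 ± 32.1 CPM and Fasn, fatty acid synthase, by −3.02 ± 0.23. Of 45 TCA cycle and oxidative phosphorylation genes, 4 rose and 13 fell (4 and 12 adjusted over the list alone; 0.204), including Idh2 (−3.10 ± 0.14) and Suclg2 (−2.02 ± 0.15), both enzymes of the TCA cycle. Of 27 M2 markers, 8 rose and 10 fell, also adjusted over the list alone (0.620). Arg1, arginase 1, rose from 0.271 ± 0.314 to 440 ± 81.3 CPM and Mrc1, the mannose receptor CD206, fell from 431 ± 34.6 to 4.35 ± 0.496 CPM. Of 32 core macrophage genes, 16 rose and 13 fell, also adjusted over the list alone (0.550), with Fcgr2b, the inhibitory Fc receptor, at 4.36 ± 0.20 and Gas6, a ligand of TAM receptors, at −4.61 ± 0.27. Of 11 MHC class II genes, 3 rose and 1 fell, also adjusted over the list alone (0.163).

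KO macrophages were compared in the same way to ask whether the M1 response proceeds without Ptprz1. Cxcl9 rose from 0 to 1504 ± 43.5 CPM (SD, n = 2), at least 10281-fold (adjusted p = 1.18e-06), Cxcl11 to 156 ± 31.8 CPM, at least 1065-fold, and Nos2 from 3 counts in all to 5452 ± 466 CPM (adjusted p = 1.75e-07). Kntc1, a kinetochore protein, was at least 190-fold lower, Pbk, a mitotic kinase, at least 139-fold lower, and E2f7 at least 91.8-fold lower. All 29 M1 markers, all 34 interferon-stimulated genes, all 20 MHC class I genes and 19 of 20 IFNγ-induced GTPases rose, also adjusted over the list alone, with Mx1 at 9.44 ± 0.73 and Iigp1 at 11.82 ± 0.65. Of the Toll-like receptor and NF-κB genes, 32 rose and 1 fell (34 and 2 adjusted over the list alone), and of the chemokines 14 rose and 4 fell, also adjusted over the list alone. Of the glycolysis genes, 16 rose and 2 fell (17 and 3 adjusted over the list alone), with Pfkfb3 at 6.46 ± 0.24 and Hif1a, a hypoxia-inducible transcription factor, at 2.72 ± 0.22. Of the cell cycle genes, 33 fell and 2 rose, also adjusted over the list alone, and of the cholesterol synthesis genes 18 fell (19 adjusted over the list alone), with Sqle at −3.21 ± 0.34. Of the lipid handling genes, 6 rose and 11 fell (6 and 12 adjusted over the list alone), with Lpl at −3.60 ± 0.23, and of the M2 markers 7 rose and 8 fell, also adjusted over the list alone, with Arg1 at 7.62 ± 0.72 and Mrc1 at −6.27 ± 0.42. EdgeR called 7203 genes, 3676 higher and 3527 lower. The camera calls of M1 markers, interferon-stimulated genes, MHC class I, GTPases, Toll-like receptor genes, chemokines, glycolysis, the cell cycle and cholesterol synthesis (largest adjusted p = 0.00101) were lost with an estimated correlation (adjusted p = 0.227 to 0.445 with an estimated correlation). Of the oxidative stress genes, 14 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0288, and adjusted p = 0.266 with an estimated correlation), and that camera call was lost without KO LPS+IFNγ library 1 (0.0714).

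Between the genotypes, 6264 genes were called after LPS+IFNγ in both, 6263 in the same direction, with 3205 higher and 3058 lower in both against 1006 and 951 for independent lists of these sizes. Across 13525 genes, which are not independent replicates, log2 fold changes in WT and KO correlated with Pearson's r = 0.907 and Spearman's ρ = 0.908, and the 2 comparisons share no control libraries. The interaction test, which asks whether the response itself differs, called 0 genes by edgeR and 6 by DESeq2. EdgeR's unadjusted p was below 0.05 for 476 genes, against 676 expected by chance. The smallest adjusted p was 0.144, for Gm20186 (2.80 ± 0.33, SE). The median SE of the interaction was 0.251 on the log2 scale. Interaction counts were 11 without KO control library 2, 27 without KO LPS+IFNγ library 1 and 1 without KO LPS+IFNγ library 2.

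**Figure D3:**
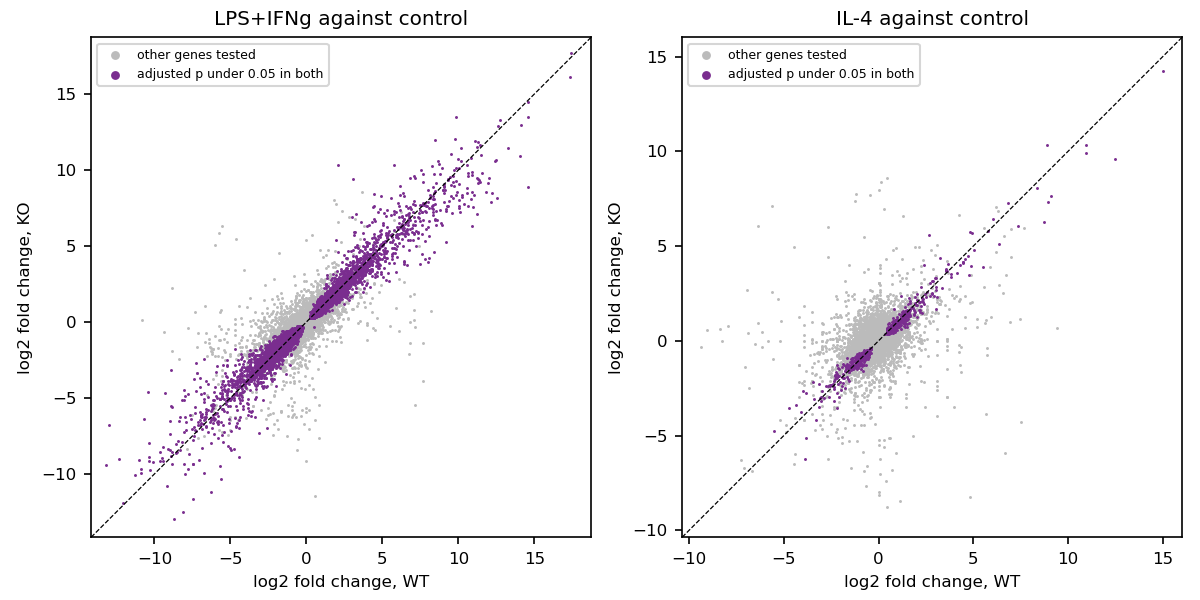
Log2 fold changes of all tested genes after LPS+IFNγ and after IL-4, with WT on the horizontal and KO on the vertical axis and 1 point per gene. Points of the LPS+IFNγ response lie closer to a line (Pearson's r = 0.907) than points of the IL-4 response (0.545). EdgeR called more genes after LPS+IFNγ (7348 in WT and 7203 in KO) than after IL-4 (1222 and 928). The 2 values of r therefore do not compare how alike the genotypes are.

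IL-4 was compared with control to describe the M2 response in WT macrophages. Retnla, the resistin-like molecule FIZZ1, rose from 0 to 231 ± 17.0 CPM (SD, n = 2), at least 1562-fold (adjusted p = 5.22e-04), and Arg1 from 0.271 ± 0.314 to 1555 ± 79.5 CPM (log2 fold change 12.46 ± 0.91, SE; adjusted p = 2.09e-04). Il31ra, a cytokine receptor chain, was at least 93.7-fold higher, Flt1, a VEGF receptor, rose by 8.72 ± 0.53, and Ocstamp, a protein of osteoclast and giant cell fusion, by 8.34 ± 0.72 to 81.8 ± 2.73 CPM. Cx3cr1, the fractalkine receptor, fell from 88.1 ± 23.2 to 1.97 ± 0.769 CPM (−5.49 ± 0.44, adjusted p = 2.77e-04) and Icosl, a costimulatory ligand, by −4.11 ± 0.33. EdgeR called 1222 genes, 665 higher and 557 lower. That count was 175 and 245 without WT control library 1 and 2, 235 and 281 without WT IL-4 library 1 and 2, and 757 and 768 without WT LPS+IFNγ library 1 and 2. DESeq2 called 1897 genes, and a fit to the 4 libraries of the contrast called 3475.

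By gene group, 22 of 27 M2 markers rose in WT macrophages and 0 fell by edgeR (23 rose adjusted over the list alone; camera adjusted p = 3.63e-25). Of 45 TCA cycle and oxidative phosphorylation genes, 18 rose (29 rose and 1 fell adjusted over the list alone; 3.95e-12), with Mdh2, mitochondrial malate dehydrogenase, at 0.78 ± 0.086. Of 11 osteoclast genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; 1.74e-04). These 3 camera calls held with an estimated correlation (adjusted p = 0.0018, 0.0195 and 0.0438 with an estimated correlation). Of 24 ER stress genes, 10 rose (15 rose and 1 fell adjusted over the list alone; 4.9e-07, and adjusted p = 0.469 with an estimated correlation), including Atf3, a stress-induced transcription factor (232 ± 13.9 to 644 ± 6.16 CPM), and Pdia4, a protein disulfide isomerase (77.3 ± 3.50 to 194 ± 15.3 CPM). Of 25 glycolysis genes, 8 rose (10 adjusted over the list alone; 4.12e-04, and adjusted p = 0.451 with an estimated correlation). Of 40 Toll-like receptor and NF-κB genes, 10 fell (14 fell and 1 rose adjusted over the list alone; 9.03e-04, and adjusted p = 0.639 with an estimated correlation), with Cd14, the LPS co-receptor, going from 240 ± 14.7 to 45.6 ± 1.42 CPM. Of 32 core macrophage genes, 3 rose and 9 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.0950, but 0.0466 and 0.0464 without KO control library 1 and 2), with Fcgr2b at 2.80 ± 0.19 and Maf, a macrophage transcription factor, at −2.24 ± 0.23. Of 20 genes of the PTPRZ axis, 5 rose, also adjusted over the list alone (0.0269, and adjusted p = 0.594 with an estimated correlation), among them Fyn, a Src family kinase, at 1.68 ± 0.10. That camera call was lost without WT control library 1 (0.196), WT IL-4 library 2 (0.190), either KO control library (0.0766 and 0.0761), either WT LPS+IFNγ library (0.0912 and 0.0923), either KO IL-4 library (0.0900 and 0.0896) or KO LPS+IFNγ library 1 (0.0626).

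In KO macrophages, IL-4 raised Retnla from 0 to 133 ± 47.1 CPM (SD, n = 2), at least 910-fold (adjusted p = 8.06e-04), Arg1 from 1.82 ± 0.810 to 1406 ± 68.9 CPM (9.60 ± 0.77, adjusted p = 3.92e-04), and Chil3, the chitinase-like protein Ym1, from 2.35 ± 3.26 to 370 ± 50.6 CPM (7.28 ± 0.92). Il31ra was at least 60.7-fold higher, Flt1 rose by 6.25 ± 0.44, and Cx3cr1 fell from 63.6 ± 20.2 to 2.38 ± 0.190 CPM (−4.74 ± 0.42, adjusted p = 5.78e-04). Of the M2 markers, 19 rose (23 adjusted over the list alone; camera adjusted p = 1.74e-22, and adjusted p = 0.00249 with an estimated correlation). Of the TCA cycle and oxidative phosphorylation genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; 6.44e-06), and of the osteoclast genes 6 rose (8 rose and 1 fell adjusted over the list alone; 4.75e-04), both at adjusted p = 0.0886 with an estimated correlation. Of the ER stress genes, 5 rose (7 adjusted over the list alone; 4.75e-04), with Atf3 at 1.42 ± 0.18. Of the core macrophage genes, 3 rose and 9 fell (3 and 12 adjusted over the list alone; 0.0052), with Fcgr2b at 3.15 ± 0.19 and Fcgr1, a high-affinity Fc receptor, at −2.47 ± 0.30. Of the Toll-like receptor and NF-κB genes, 1 rose and 9 fell (1 and 13 adjusted over the list alone; 6.66e-04, lost without KO control library 1, 0.0541, or KO IL-4 library 2, 0.0548). These 3 camera calls had adjusted p = 0.615 with an estimated correlation. EdgeR called 928 genes, 476 higher and 452 lower. The count was 303 without KO control library 1, 486 and 495 without WT control library 1 and 2, 554 and 558 without WT LPS+IFNγ library 1 and 2, and 424 without KO IL-4 library 2. DESeq2 called 1673 and edgeR without the filter 1620, while a fit to the 4 libraries of the contrast called 8, where Il31ra, Chil3, Flt1, Atf3 and Fcgr1 had adjusted p-values of 0.0572, 0.118, 0.0517, 0.105 and 0.105.

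Interferon-stimulated genes and cell cycle genes had lower values after IL-4 in KO macrophages, the former largely through KO control library 1. Of 34 interferon-stimulated genes, 8 fell (30 adjusted over the list alone; camera adjusted p = 2.38e-11, and adjusted p = 0.615 with an estimated correlation), and DESeq2 called 27. Mean log2 CPM over the list was 4.64 and 2.56 in the control and 1.92 and 1.93 in the IL-4 libraries. Without KO control library 1, the median went from −2.14 to −0.47 (camera adjusted p = 3.89e-06), and edgeR called 0 over all genes or adjusted over the list alone, with 8 lower at an unadjusted p below 0.05. The count over all genes was also 0 without either WT control or WT LPS+IFNγ library or KO IL-4 library 2, 2 or 3 without KO IL-4 library 1 or either WT IL-4 library, and 31 without KO control library 2. Adjusted over the list alone it was 0 without KO IL-4 library 2 and 15 without KO IL-4 library 1. In WT macrophages, edgeR called 0 of the 34, 1 was lower at an unadjusted p below 0.05 and DESeq2 called 0 (camera adjusted p = 0.349). Ifit3 went from 19.3 ± 24.3 to 0.479 ± 0.0591 CPM (−5.31 ± 1.31, adjusted p = 0.0437), a call lost with 10 of the 12 libraries left out in turn (0.0505 to 0.283) and held without KO control library 2 or KO LPS+IFNγ library 2. Without KO control library 1 its value was −2.11. Of 35 cell cycle genes, 9 fell (20 adjusted over the list alone; 2.84e-08, and adjusted p = 0.196 with an estimated correlation). The same list had 3 falls in WT macrophages, also adjusted over the list alone, and a camera adjusted p of 0.0170 (adjusted p = 0.639 with an estimated correlation) that was lost without WT control library 1 (0.0605) or WT IL-4 library 2 (0.0718).

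After IL-4, 627 genes were called in both genotypes, all in the same direction, with 331 higher and 296 lower in both against 23.4 and 18.6 for independent lists of these sizes. Across 13525 genes, which are not independent replicates, Pearson's r between the WT and KO log2 fold changes was 0.545 and Spearman's ρ was 0.591. The interaction test called 0 genes by edgeR and 6 by DESeq2. EdgeR's unadjusted p was below 0.05 for 604 genes, against 676 expected by chance. The smallest adjusted p was 0.616, for Neat1 (1.64 ± 0.23, SE), and the median SE was 0.248 on the log2 scale. Without KO control library 2, the count was 12.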

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

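The results below were picked because the response to a stimulus differed between KO and WT macrophages in the camera test of the interaction, which was planned.

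Interferon-stimulated genes had interaction values below 0, that is, log2 responses that were lower in KO than in WT macrophages. The median over 34 members was −1.12 for LPS+IFNγ (camera adjusted p = 1.07e-05, and adjusted p = 0.996 with an estimated correlation) and −1.79 for IL-4 (1.45e-12, and adjusted p = 0.809 with an estimated correlation). With the 1 member that had no counts in a group set to its floor, the IL-4 median was −1.64. No member passed edgeR's interaction test, 6 and 10 members were lower at an unadjusted p below 0.05, and DESeq2 called 0. For LPS+IFNγ, the camera call was lost without KO LPS+IFNγ library 1 (0.152), and the direction reversed without KO control library 1 (0.752). For IL-4, the median was −0.22 without KO control library 1 (adjusted p = 0.0151). In KO control library 1, the mean log2 CPM of the list was 4.64, against 2.56 in KO control library 2 and 2.62 and 2.60 in the WT control libraries.

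In the LPS+IFNγ interaction, glycolysis genes had a median of −0.27 (camera adjusted p = 0.00534) and cholesterol synthesis genes a median of −0.36 (0.0012), both at adjusted p = 0.996 with an estimated correlation. The glycolysis call was lost without WT control library 2 (0.122), KO control library 2 (0.0537), WT LPS+IFNγ library 1 (0.287, median −0.12) or KO LPS+IFNγ library 1 (0.152), and the cholesterol synthesis call without KO control library 2 (0.429, median −0.0927) or KO LPS+IFNγ library 1 (0.0825). In the same interaction, the number of lists called by camera was 0 without KO LPS+IFNγ library 1, against 3 with all libraries, and 5 without KO LPS+IFNγ library 2 or either KO control library.

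In the IL-4 interaction, IFNγ-induced GTPases had a median of −0.80 (camera adjusted p = 0.0106), or −0.77 with members at 0 counts set to the floor, and cholesterol synthesis genes a median of −0.21 (0.0121), both at adjusted p = 0.832 with an estimated correlation. Mitochondrially encoded transcripts had a median of −0.67 (2.78e-04), ER stress genes −0.21 (0.00338), glycolysis genes −0.19 (0.0382), cell cycle genes −0.12 (5.33e-04) and M2 markers −0.0279 (0.0408), or −0.11 with members at 0 counts set to the floor. These 5 lists were at adjusted p = 0.809 with an estimated correlation. TCA cycle and oxidative phosphorylation genes had a median of −0.12 (3.95e-04, and adjusted p = 0.571 with an estimated correlation). The call for mitochondrially encoded transcripts was lost without KO IL-4 library 2 (median −0.22, adjusted p = 0.301), in which their mean log2 CPM was 8.21, against 9.51 in KO IL-4 library 1 and 9.23 and 9.49 in the WT IL-4 libraries. Camera calls were also lost without KO IL-4 library 2 for IFNγ-induced GTPases (0.0887), glycolysis (0.0887), cell cycle (0.103) and M2 markers (0.482). Without KO IL-4 library 1 they were lost for IFNγ-induced GTPases (0.0574), cholesterol synthesis (0.990, with the direction reversed), ER stress (0.379), glycolysis (0.154) and TCA cycle and oxidative phosphorylation genes (0.0574). Without WT IL-4 library 1 they were lost for cholesterol synthesis (0.0774), ER stress (0.0518), glycolysis (0.345) and M2 markers (0.0678). Without KO control library 1 they were lost for IFNγ-induced GTPases (0.658), cell cycle (0.186) and M2 markers (0.173), without KO control library 2 for cholesterol synthesis (0.996) and glycolysis (0.209), and without WT control library 2 for cholesterol synthesis (0.0526) and glycolysis (0.198). Medians moved towards 0 without KO control library 1 for IFNγ-induced GTPases (−0.0267), without WT IL-4 library 2 for the same list (−0.50), without KO control library 2 for mitochondrially encoded transcripts (−0.45), and without KO IL-4 library 1 for ER stress (−0.0752), cholesterol synthesis (−0.0241) and TCA cycle and oxidative phosphorylation genes (−0.0774). Medians were above 0 without KO control library 1 (0.13) or KO IL-4 library 2 (0.0606) for cell cycle genes, without KO IL-4 library 2 (0.15) or WT IL-4 library 2 (0.0177) for M2 markers and without KO control library 2 (0.0496) for cholesterol synthesis genes. Some medians moved away from 0. Without KO IL-4 library 1, these were mitochondrially encoded transcripts (−1.35), M2 markers (−0.53) and cell cycle genes (−0.44). Without KO control library 2, they were IFNγ-induced GTPases (−1.12), M2 markers (−0.44) and cell cycle genes (−0.42). Cholesterol synthesis genes were at −0.47 without KO control library 1. Without KO IL-4 library 2 they were at −0.44, and ER stress genes at −0.35. Without KO IL-4 library 1, and likewise without KO IL-4 library 2, camera called 4 lists in this interaction, against 9 with all libraries.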

How the results depend on the processing

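The fits without X and Y genes and those without all KO libraries of 1 number were chosen after the results were seen. Where a value below differs from the reported result, the cause was not tested unless stated. Without the low-count filter, edgeR called 107, 81, 33 and 312 genes between KO and WT in control, LPS+IFNγ, IL-4 and for the mean, 1620 for IL-4 in KO macrophages, and 8 and 23 in the LPS+IFNγ and IL-4 interactions. DESeq2 called 68, 34, 18 and 94 between genotypes, 1897 and 1673 for IL-4 in WT and KO macrophages, and 6 in each interaction. Fits to the libraries of 1 contrast called 4 genes between genotypes in control and 5 in IL-4 cells, and 3475 and 8 for IL-4 in WT and KO macrophages. With a minimum absolute log2 fold change of 1, the counts were 4334 and 4221 for LPS+IFNγ and 507 and 418 for IL-4. Without the KO libraries numbered 1, edgeR called 1154, 1944, 944 and 2797 genes between genotypes, and without those numbered 2, 146 in control. Fits without the KO libraries of 1 number leave 1 KO library per treatment. Their spread comes from the WT pairs, which differed less (chi-square per gene 7.10 to 15.6) than the KO pairs (48.4 to 54.9). KO libraries numbered 2 and 1 also differed, in 650 genes, so these counts do not measure the genotype effect. Without X and Y genes, which removes calls by construction, 5, 3, 4 and 13 were left. DESeq2 size factors and a stricter filter kept all 10 gene counts within 1.5 times.

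With 1 library left out, counts ran from 8 to 49, 7 to 504, 8 to 20 and 15 to 130 between genotypes, 5669 to 7658 and 5987 to 7378 for LPS+IFNγ, 175 to 1637 and 303 to 1218 for IL-4, and 0 to 27 and 0 to 12 for the interactions. A lone library was assumed to vary like the other groups. Lists called by camera ran from 5 to 14, 4 to 8, 6 to 9 and 5 to 13 between genotypes, 11 to 12 and 10 to 14 for LPS+IFNγ, 7 to 10 and 12 to 16 for IL-4, and 0 to 5 and 4 to 13 for the interactions. With an estimated correlation, camera called 1 list in each genotype contrast, 0 for LPS+IFNγ in either genotype, 3 and 1 for IL-4 in WT and KO macrophages, and 0 in both interactions. Fry called 1 in each genotype contrast, 25 for LPS+IFNγ in both genotypes, 4 for IL-4 in KO macrophages and 0 in both interactions.

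Directions reversed for interferon-stimulated genes without KO control library 1, both between genotypes in control (adjusted p from 3.54e-60 to 0.924 over the left-out libraries) and in the LPS+IFNγ interaction (1.04e-43 to 0.752). Between genotypes in control, Ifit3 ran from −0.280 without KO control library 1 to 3.87 and was −0.280 without all KO libraries numbered 1. Between genotypes after LPS+IFNγ, Asns ran from −0.0222 without KO LPS+IFNγ library 2 to 1.34 and was −0.0322 without all KO libraries numbered 2. Csf1 for IL-4 in WT macrophages ran from −0.422 without WT IL-4 library 2 to 2.46. For genes near Ptprz1, Fisher's exact test gave p = 0.0715 in a 50 Mb window (0.0234 against other autosomal genes alone) and 1 in LPS+IFNγ cells, where 0 were called. Of 4678 values of named genes under the alternatives, 4363 kept direction and side of the threshold, 205 no longer passed, 105 newly passed and 5 reversed.

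Library numbers are not established to pair the samples. With the number as a block, edgeR called 27, 21, 36 and 173 genes between genotypes, camera called 7 lists for the mean, and a block within genotype gave 2064 and 1577 for IL-4. Across 10944 genes, differences between number 2 and 1 correlated above 0.1 in 14 of 15 pairs of groups, from −0.0123 to 0.462.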

Other observations

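The comparison of libraries by number and all tests of explanations below, except the count of all genes over other divisions of the libraries, were chosen after the results were seen.

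Within each genotype, libraries numbered 2 differed from libraries numbered 1. The 3 libraries of a number are the 3 treatments, and their differences by number correlated between treatments within each genotype. They may share an animal or culture, so the SEs, p-values and counts below treat possible repeats as independent. In WT libraries, Sparc, a collagen-binding matrix protein (log2 difference 2.18 ± 0.11, SE, 3 libraries per number), Cxcl12, a chemokine of marrow stroma (2.65 ± 0.15), and Col6a1, a type VI collagen chain (2.11 ± 0.11), were higher in number 2 (adjusted p = 1.79e-04 for all 3). Col1a1 was higher by 2.14 ± 0.18 in WT and 1.73 ± 0.18 in KO libraries, and Postn by 2.06 ± 0.29 and 2.46 ± 0.19. Of 16 stromal markers, 13 were higher in number 2 in WT libraries, and 10 were higher and 1 lower in KO libraries, in both cases also adjusted over the list alone. The endothelial markers of this list, Pecam1, Cdh5 and Kdr, were not among the higher ones in either genotype. The 1 lower in KO libraries was Pecam1 (−2.46 ± 0.18). In WT libraries, edgeR called 124 genes, 120 higher and 4 lower, and in KO libraries 650, 339 higher and 311 lower. The genotypes shared 82 genes, all higher in number 2, against 3.01 for independent lists. In KO libraries, 6 of 11 MHC class II genes were lower in number 2, also adjusted over the list alone, including the invariant chain Cd74 (−1.46 ± 0.20), and so were 3 of 9 granulocyte markers (4 adjusted over the list alone). Camera gave an adjusted p of 6.43e-04 for both lists, and adjusted p = 0.508 and 0.546 with an estimated correlation.

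Other lists after LPS+IFNγ in WT macrophages gave these counts of edgeR calls, with the same counts adjusted over the list alone unless stated. Of 29 repair and fibrosis genes 13 rose and 7 fell, of 20 PTPRZ axis genes 5 rose and 5 fell, of 21 immediate early and heat shock genes 9 rose and 2 fell (9 and 1 adjusted over the list alone), and of 13 mitochondrially encoded transcripts 6 fell. Of 6 dendritic cell markers 2 rose, of 4 mast cell and basophil markers 1 rose, of 4 T and NK cell markers 2 fell, and of 4 erythroid and megakaryocyte markers 2 fell (none adjusted over the list alone). Camera adjusted p was 0.0267 for the immediate early and the mitochondrial list, and adjusted p = 0.492 and 0.648 with an estimated correlation.

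The real division of the libraries by genotype called 23 genes for the mean over treatments, and of 100 divisions that keep 2 against 2 libraries within each treatment, 1 called as many, the real one, and the highest other called 3. Sex divides the libraries in the same way, and Xist and 4 Y-linked transcripts alone outnumber the highest other, so this count decides nothing for other genes. Adjusted over autosomal genes alone, the real division called 11 and the highest other 3, and 1 of the 100 called as many, the real one, but libraries of 1 genotype with the same number were alike, and kept together they allow 3 divisions (11, 0 and 0 genes), too few for a share below 0.05. Xist and the 4 Y-linked transcripts follow the sex of the mice, which went with genotype in 12 of 12 libraries. For the other 18 genes, 5 of them on X or Y, the effects of sex and of Ptprz1 loss cannot be told apart, because sex and genotype parted in 0 libraries, and a difference in strain background, which the labels leave open, was not tested.

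Met and Gm20186, both within 6 Mb of Ptprz1, were lower in KO libraries. Called genes were denser within 20 Mb of Ptprz1 (Fisher's exact test, p = 0.0227), which may reflect DNA of the strain in which the allele was made, carried along with it, as a hypothesis that rests on these 2 genes and gave p = 0.0715 in a 50 Mb window, or 0.0234 there and 0.0070 within 20 Mb against other autosomal genes alone. Loss of reads at strain variants alone would leave the same fold under each treatment, but the fold was smaller after LPS+IFNγ for Met (interaction 1.36 ± 0.21, SE) and Gm20186 (2.80 ± 0.33). Adjusted over these 2 genes, picked after the data were seen, p was 1.08e-04 and 2.13e-05, and adjusted over all genes 0.562 and 0.144. Because of that choice, loss of reads at strain variants is not excluded. An effect of Ptprz1 loss or of sex on either gene stays open and was not tested apart.

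Stromal markers had higher values in KO libraries, with a median of 1.31 for the mean over treatments. Their median difference between libraries numbered 2 and 1 was 2.16 in WT and 1.11 in KO libraries, so the markers also part libraries of 1 genotype, and differing numbers of stromal cells in the cultures may account for both. A lower share of macrophages would raise every other cell type, and B cell markers had a median KO minus WT difference of −1.77, with 3 of 5 lower adjusted over the list alone, but 4 of the 5 had a mean log2 CPM below 1, too low to exclude it. None of the 5 passed edgeR's test over all genes, 3 were lower at an unadjusted p below 0.05 and DESeq2 called 1. B cell markers also parted libraries of 1 genotype. Their median difference between libraries numbered 2 and 1 was 1.69 in WT and −0.73 in KO libraries. For the mean, medians were −0.36 for granulocyte, −0.49 for mast cell and basophil, and −0.18 for erythroid and megakaryocyte markers. They were −0.06 for T and NK cell and 0.17 for dendritic cell markers, and 0.018 for core macrophage genes. With 4 to 9 members tested per cell type, these medians do not decide it either. A lower share of macrophages, expression of stromal genes by the macrophages and an effect of genotype stay open.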
